A study of Caenorhabditis elegans with 2 samples.

How the data were processed

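TRA-1 was mapped by chromatin immunoprecipitation and sequencing in 2 biological replicates of whole L4 larvae that carry a GFP tag on tra-1. The authors deposited peak lists on the ce11 build, per the file names. For the whole series there were 2 thresholded and 2 ranked lists made from both replicates, and for each replicate 1 thresholded and 1 ranked list made from that replicate alone. Per the descriptions of the files, the lists derive from alignments of the replicates and of a control. The thresholded lists also derive from a further bed file that these descriptions do not explain. The control alignments were not analysed here. The aligner and the peak caller are not given in the sources used here, and the lists hold no read counts, so depth is unknown.

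In the deposited lists each peak has a score, a whole number that rises as the irreproducible discovery rate (IDR) falls, and the lowest score in each thresholded list was 830, an IDR of about 0.01. The signal of each peak is the value deposited by the authors and was used only to rank and describe peaks within a list. The deposited −log10 values of q were read and entered no test. The ranked list of both replicates gives a signal for each of the 2 replicates without their numbers, so the values printed per replicate come from the strongest overlapping peak of each replicate's own ranked list.

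All 2703 sites of the main list were found in its ranked list, where 2778 passed the same score. Positions were compared with the Ensembl release 115 annotation of WBcel235, whose sequence ce11 shares, and no peak ran past a chromosome end. Coordinates are 1-based. Of the gene names in the 26 lists, 3 had no protein-coding match under that name and were left out.

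The tests and the main list were fixed before the data were examined. Replicate overlap, promoter share and noncoding classes were set against 1000 random placements within the same chromosomes. The X share was tested with an exact binomial test, the core with exact McNemar tests against windows 500 bp to each side, and words and gene lists with Fisher's exact test and Benjamini-Hochberg adjustment. A protein-coding gene was called bound when a summit lay from 2000 bp upstream of its start to its end. These tests count sites or genes of pooled lists, not samples, and Wilson intervals cover counting error only. The named genes were the 20 sites with the highest signal, every member of the sex determination, earlier target and DM-domain lists, and up to 6 bound members of each other list past the threshold.

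The alternatives were the second thresholded list, the stronger part of the main list, each replicate alone, other windows, overlaps, backgrounds, word lengths and gene assignments, and 10000 random lists matched on the length of the gene and its upstream region. The planned stricter threshold of 0.01 was the one the authors had applied, so an IDR of at most 0.001 was added after the data were seen.

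The whole procedure was tested on simulated data. It recovered 301 sites for 300 planted exact cores among 2703, 800 of 800 sites planted on X, and 43 bound ribosomal protein genes for 40 planted. It called 159 words as more frequent, or 15 with tRNA sites left out, where the planted core is made up of 3 words. Fisher's exact test called 3 of 25 gene lists with nothing planted, and the matched random lists called 0, so both are given. The unplanted simulated sites lay at random along the chromosomes, so how often either test makes false calls on sites concentrated at promoters was not measured. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.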

Results

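The series asked where TRA-1 binds the genome of *Caenorhabditis elegans* larvae. TRA-1 is a zinc-finger transcription factor of the GLI family and the last regulator of the somatic sex determination pathway. The tra-1 gene was tagged with GFP at its own locus by CRISPR, and chromatin from whole L4 larvae aged 48 h was precipitated with an antibody against GFP. There were 2 biological replicates of 1 group, and the sex of the animals was not recorded in the labels. The data used were peak lists on the ce11 build. The main list, made by the authors from both replicates, held 2703 sites covering 0.772 Mb in 2580 separate regions, and a second thresholded list of both replicates held 3168. Replicate 1 alone gave 1682 sites and replicate 2 alone gave 1355. The lists carry no read counts, so the depth of each library is unknown. The signal of a site is the authors' own peak value and ranks sites within a list only.

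The strongest site of the main list lay upstream of fog-1, a gene required for sperm fate in the germ line. Its summit at position 3210472 of chromosome I was 574 bp upstream of the fog-1 start, outside protein-coding genes, with a signal of 894.7. At this site the peak signal was 458.4 in replicate 1 and 425.2 in replicate 2. Of the 20 strongest sites, fog-1 was the single one with an exact copy of the TRA-1 core sequence, TGGGTGGTC. The next sites lay at rnf-113, K01G5.10 and tasp-1 on chromosome III (signal 765), at rpl-3 on III (758.6) and 3692 bp from the start of jmjd-3.1 on X (700.9). Among the other strong sites, 3 of the 20 lay at ribosomal protein genes, namely rpl-3, rpl-15 (with K11H12.1 and K11H12.8) and rpl-35. Others lay at mog-4, a germline sex determination gene, at F44E5.4 and F44E5.5, and at rpa-2, fbxl-5, cdc-48.1 with C06A1.7, eel-1 and pxn-1. The 8 sites assigned to no gene were nearest to jmjd-3.1, K07D4.2, K08F11.1 (for a pair of sites), bcat-1, fbxb-95, asp-13 and C08E8.3. Of the 20 sites, 18 lay outside protein-coding genes and 2, at fbxl-5 and pxn-1, lay in introns.

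The replicates shared many sites. Of the sites of replicate 1, 956 of 1682 (56.8%, 95% Wilson interval 54.5 to 59.2%) overlapped a site of replicate 2, against a mean of 0.736% for random placements within the same chromosomes. In the other direction 961 of 1355 sites (70.9%, interval 68.4 to 73.3%) overlapped, against 0.937%. Both one-sided permutation tests gave p = 0.001, the smallest that 1000 placements can give. Across the 2703 sites of the main list, the peak signals of the replicates had a Spearman correlation of 0.558, and across all 78883 ranked sites one of 0.3055, a description across sites, which are not independent replicates. The main list was selected for agreement of the replicates. Of the main sites, 954 (35.3%) were in both replicates' own lists and 936 (34.6%) were in neither.

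TRA-1 sites were concentrated outside coding sequence and near gene starts. Of the main sites, 60.3% lay outside protein-coding genes, against a mean of 37.6% for random placements, while 6.59% lay in coding exons, against 24.3%. Introns held 28.4% of sites, against 33.1%, and 5' UTRs held 2.92%, against 1.43%. Promoters, taken as 1000 bp upstream to 200 bp downstream of a protein-coding transcript start, held 43.4% of summits, against 25.8% of random placements. The two-sided permutation test of the promoter share gave p = 0.002, the smallest that 1000 placements can give.

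The X chromosome held more sites than its length predicts. It carried 666 of the 2703 sites (24.6%, 95% Wilson interval 23.1 to 26.3%) and makes up 17.7% of the nuclear genome (exact two-sided binomial test, p = 1.03e-19). X had 37.6 sites per Mb, chromosome II 29.8, III 28.7, I 25.8, V 21 and IV 20.4. X also had the highest density in each replicate's own list, at 25.9 sites per Mb in replicate 1 and 19.9 in replicate 2. X carries 45.1% of the tRNA genes, and 144 of its 666 sites lay within 500 bp of one. Without all sites near tRNA genes, X held 21.7% of the rest. These tests count sites, which are not independent samples.

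**Figure D1:**
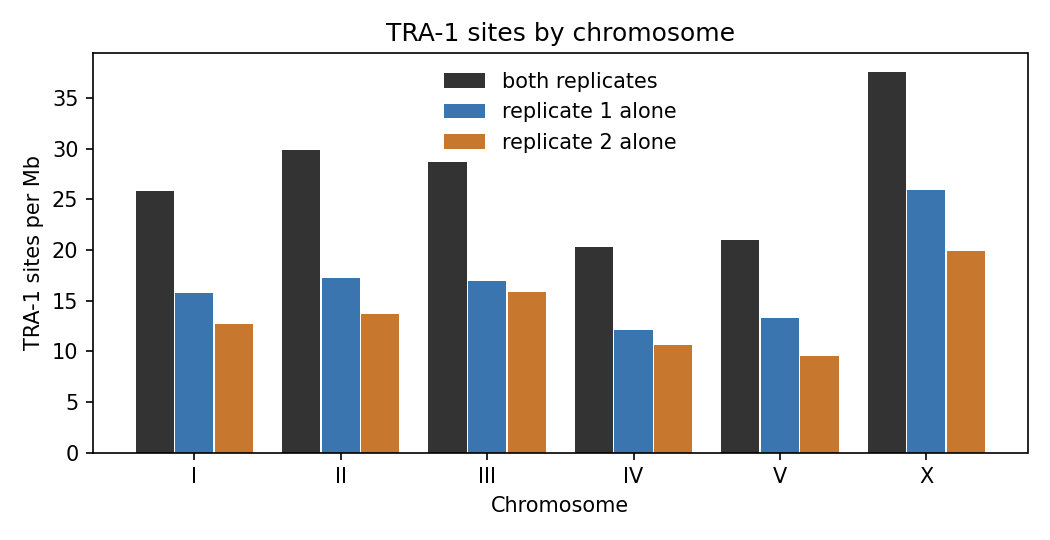
TRA-1 sites per Mb (vertical axis) on each chromosome (horizontal axis) for the list of both replicates and for each replicate's own list. X stands highest in all 3 lists, at 37.6 sites per Mb for both replicates.

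The TRA-1 core sequence was present at few sites. With at most 1 mismatch, TGGGTGGTC lay within 50 bp of the summit of 58 of 2703 sites (2.15%, 95% Wilson interval 1.66 to 2.76%), including the fog-1 site and both sites upstream of fog-3. Windows 500 bp to the left held it at 35 sites (1.29%) and windows to the right at 24 (0.888%). The exact McNemar tests, two-sided, gave p = 0.022 against the left flank and p = 1.49e-04 against the right. The windows differed in base composition, with 45.8% G and C at the summits and 35.8% and 35.6% in the flanks, and 263 of the 503 other orders of the same 9 bases had a centre to flank ratio as high as the core's 1.95. An exact core lay within 50 bp of 8 summits, at fog-1, hbl-1, snpc-1.3, T28B11.1, sod-4, F10A3.4 and, at a pair of sites, fog-3. Of these, snpc-1.3, T28B11.1, sod-4 and F10A3.4 fall outside the rule for named genes and were chosen after their values were seen. Of the 675 sites with the highest signal, 2.52% held the core, and of the 675 with the lowest, 1.63% did, a difference that did not pass Fisher's exact test (two-sided, p = 0.34).

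**Figure D2:**
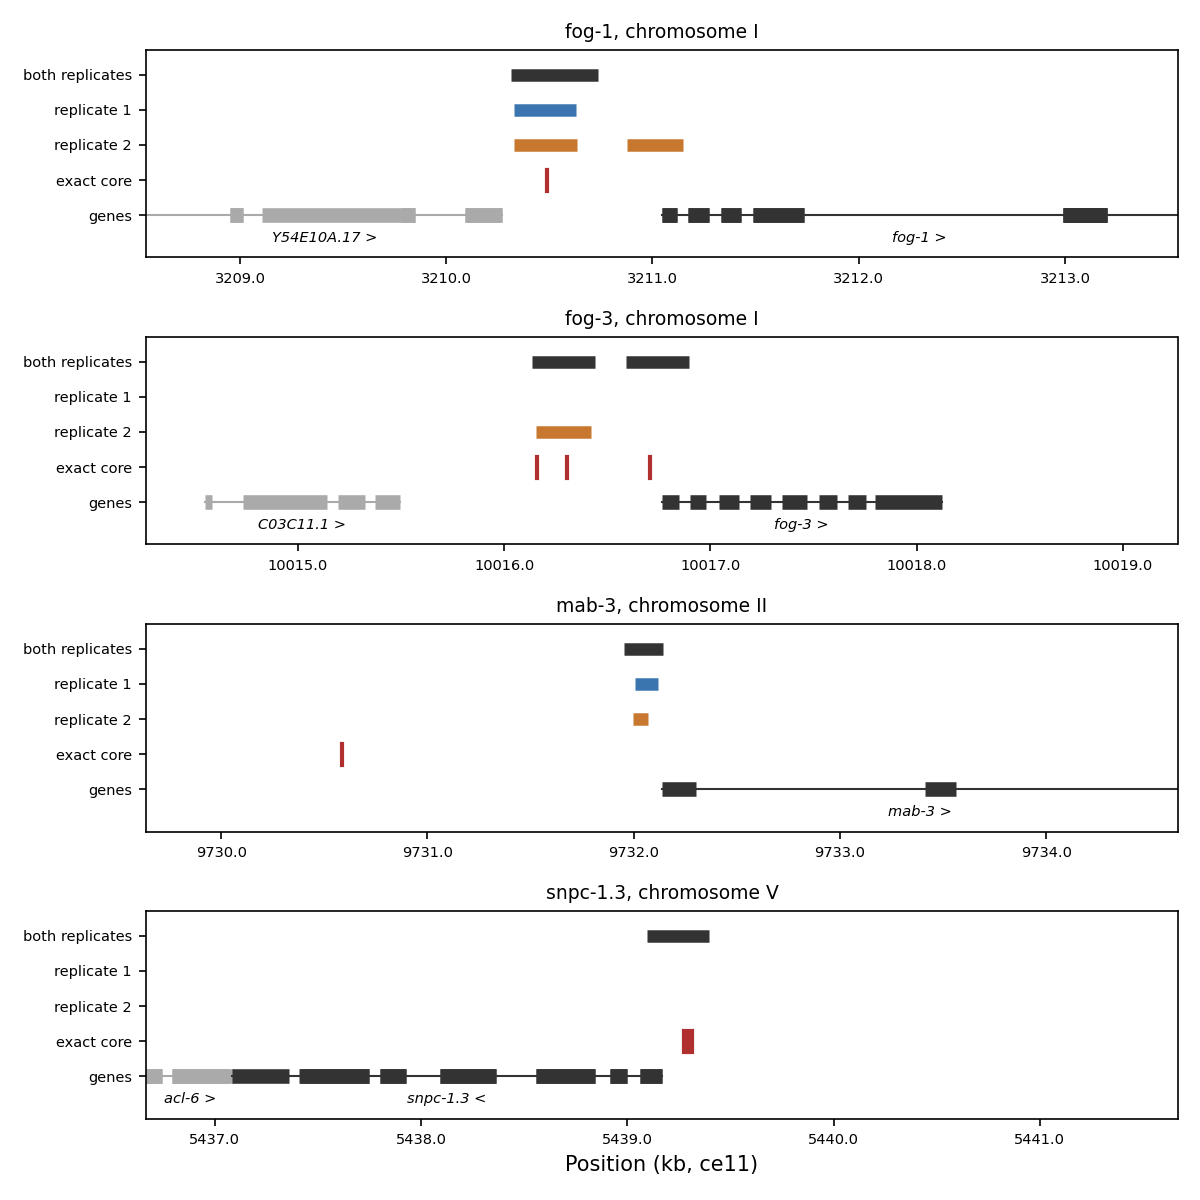
Sites of the list of both replicates and of each replicate's own list, exact copies of the core and protein-coding genes (rows) around 4 gene starts, by position in kb on ce11 (horizontal axis). The 4 genes were chosen for the plot after their values were seen. The fog-1 and fog-3 sites contain exact cores, the mab-3 site contains none, the snpc-1.3 site is in neither replicate's own list, and no fog-3 site is in the list of replicate 1.

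Many words of 7 bases differed in frequency between the summits and the flanks, which also differed in base composition. Among the words more frequent at summits, the one with the lowest p was CTTATCA, the reverse complement of TGATAAG, a sequence of the kind bound by GATA factors, at 9.29% of summits against 1.98% of flank windows. GGTTCGA, a sequence found within tRNA genes, lay at 6.36% of summits against 0.906%, and without sites near tRNA genes at 1.7% against 0.768%. CTCTCTC lay at 8.44% against 1.89%, and GAGACGC at 6.51% against 1.04%. Of 8192 words, 1831 were more frequent and 1041 less frequent at summits (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). Of the words within the core, GGGTGGT lay at 1.63% of summits against 0.518% and TGGGTGG at 1.63% against 0.647%, and they ranked 437 and 708 by p among the words more frequent at summits. The third, GGTGGTC, lay at 1.26% against 0.74% and did not pass Fisher's exact test (adjusted p = 0.0667). With sites that did not pass the threshold as the background, 803 words were more frequent. The windows of these sites held 40.25% G and C, the summits 45.77% and the flanks 35.8% and 35.57%. Neither count of words was controlled for base composition. GGGTGGT passed Fisher's exact test against this background (adjusted p = 0.00147), and TGGGTGG (adjusted p = 0.118) and GGTGGTC (adjusted p = 0.834) did not. This background drew on 2703 sites, fewer windows than the flanks to each side of every summit. GGGTGGT lay at 0.518% of either background, with a lower adjusted p against the flanks (Fisher's exact test, 1.85e-05). The number of words called may therefore partly reflect the size of the background.

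Genes named as TRA-1 targets in earlier work were bound more often than other genes. Of the 12 genes, 7 had a site from 2000 bp upstream of the start to the gene's end, against 11.2% of other protein-coding genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 26 lists, p = 5.38e-04). They were fog-1, mab-3, sup-26, daf-16, xol-1, lin-39 and fog-3. The mab-3 summit lay 76 bp upstream of its start (signal 325.5), that of sup-26 1920 bp upstream (321), that of xol-1 135 bp upstream (141.7) and that of lin-39 in its 5' UTR (108). Of the 5 sites of daf-16, the strongest lay 376 bp upstream of its start (190.8). The sites of fog-3 lay 477 bp (89.3) and 20 bp (82.1) upstream of its start. With at most 1 mismatch, the core lay in the sites of fog-1, fog-3 and xol-1. No site of mab-3, sup-26, daf-16 or lin-39 held it. For unbound members, distances are from the nearer edge of the gene. The nearest site lay 2718 bp past the end of fkh-6 and 6539 bp from its start. That of dmd-3, within 100 bp of a small nucleolar RNA gene, lay 6788 bp past its end and 9509 bp from its nearest start. That of ceh-30 lay 9015 bp upstream, and egl-1 and fem-3 had none within 10000 bp. No fog-3 site was in the list of replicate 1 alone, and the lin-39 site was not in that of replicate 2.

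In the sex determination pathway, 3 of 17 genes were bound, namely tra-1, xol-1 and sup-26, a share that did not pass Fisher's exact test against other genes (adjusted p = 0.742). The tagged gene tra-1 had 7 sites, of which the strongest lay 556 bp upstream of its start (signal 137.2) and the other 6 lay in introns. Some overlap, so that the 7 make up 5 separate regions. Each replicate's own list held 2 sites at tra-1, and 1 of the 7 had an IDR of at most 0.001. Of the 14 unbound genes, 6 had a site within 10000 bp of the gene's nearer edge. The nearest site lay upstream of ceh-39 (2671 bp), tra-2 (2792 bp), sdc-1 (4434 bp) and sdc-2 (7128 bp). Past the gene's end lay those of cul-2 (1511 bp, 6441 bp from its nearest start) and fem-2 (2842 bp, 5449 bp from its start). The ceh-39 and sdc-1 sites lay within 100 bp of a tRNA gene, and the tra-2 site within 100 bp of a small nuclear RNA gene. All of these were assigned to other genes. The other 8 unbound genes, sdc-3, her-1, tra-3, fem-1, fem-3, sex-1, fox-1 and sel-10, had no site within 10000 bp. In the DM-domain family, whose members include regulators of male development, mab-3, dmd-7 and dmd-10 were bound out of 10 genes (Fisher's exact test, adjusted p = 0.266). With each site given to its nearest start only, 4 were bound and the list passed (Fisher's exact test, adjusted p = 0.0345). The dmd-10 site was in neither replicate's own list. The strongest of the 3 sites of dmd-7 lay 196 bp upstream of its start (signal 223.6), and dmd-7 had 2 sites in the list of replicate 1 and 1 in that of replicate 2. Of the unbound members, dmd-6 had a site 5426 bp upstream and dmd-5 one 7876 bp upstream. Past the gene's end lay those of dmd-8 (716 bp, 2565 bp from its start) and dmd-3 (6788 bp, described above). No site lay within 10000 bp of mab-23, dmd-4 or dmd-9.

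All 6 vitellogenin genes, which encode yolk proteins, were bound (Fisher's exact test, adjusted p = 1.69e-05), with the strongest site at vit-3 (signal 250.3), followed by vit-2, vit-4, vit-5, vit-1 and vit-6. Some of these genes are close copies of each other, and reads shared between them could not be told apart here. Except for vit-6, on IV, the vitellogenin genes lie on X. Their signals in replicate 1 and replicate 2 were 189.3 and 63.84 at vit-3, 100.6 and 44.63 at vit-2, and 98.56 and 47.93 at vit-4. They were 95.97 and 41.43 at vit-5, 78.74 and 38.59 at vit-1, and 65.45 and 59.25 at vit-6. Across main sites, 94.3% had paired signals in the ranked list within 2-fold. Ribosomal protein genes were bound at 33 of 78 (42.3%, Fisher's exact test, adjusted p = 2.88e-11), led by rpl-3, rpl-15, rpl-35, rpl-11.2, rpl-20 and rps-1. Of 12 heterochronic genes, which time larval development, 8 were bound (Fisher's exact test, adjusted p = 5.16e-05), with the strongest sites at daf-12, lin-46, hbl-1, lin-14, lin-41 and blmp-1. With promoters only, 3 heterochronic genes were bound and the list did not pass (Fisher's exact test, adjusted p = 0.139). Of 16 genes of vulval, EGF or Notch signalling, 6 were bound (Fisher's exact test, adjusted p = 0.025), namely egl-17, lag-1, mpk-1, let-60, lin-39 and let-23. This group of genes did not pass Fisher's exact test in the second thresholded list (adjusted p = 0.133), in replicate 1 alone (0.337), in replicate 2 alone (0.0644) or with promoters only (0.547). Chemoreceptor genes were bound less often, at 19 of 1014 (1.87%, Fisher's exact test, adjusted p = 2.3e-29), with the strongest sites at srd-43, srz-62, srh-2, srh-70, srh-269 and srg-69. In replicate 1 alone and replicate 2 alone, whose lists are shorter, the bound genes numbered 6 and 4 for vitellogenins, 23 and 21 for ribosomal proteins, 7 and 5 for heterochronic genes, 3 and 4 for vulval, EGF or Notch genes, and 15 and 12 for chemoreceptors. On simulated sites Fisher's test also called 3 of 25 lists with nothing planted in them, chemoreceptors among them, so random lists matched on the length of the gene and its upstream region were used beside it. Unlike the real sites, the unplanted simulated sites were not concentrated at promoters. With 10000 matched lists the adjusted permutation p, two-sided, was 0.0104 for the earlier targets, 0.0026 for heterochronic genes and 0.00173 each for vitellogenins, ribosomal proteins and chemoreceptors, while vulval, EGF or Notch genes did not pass (adjusted p = 0.277).

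**Figure D3:**
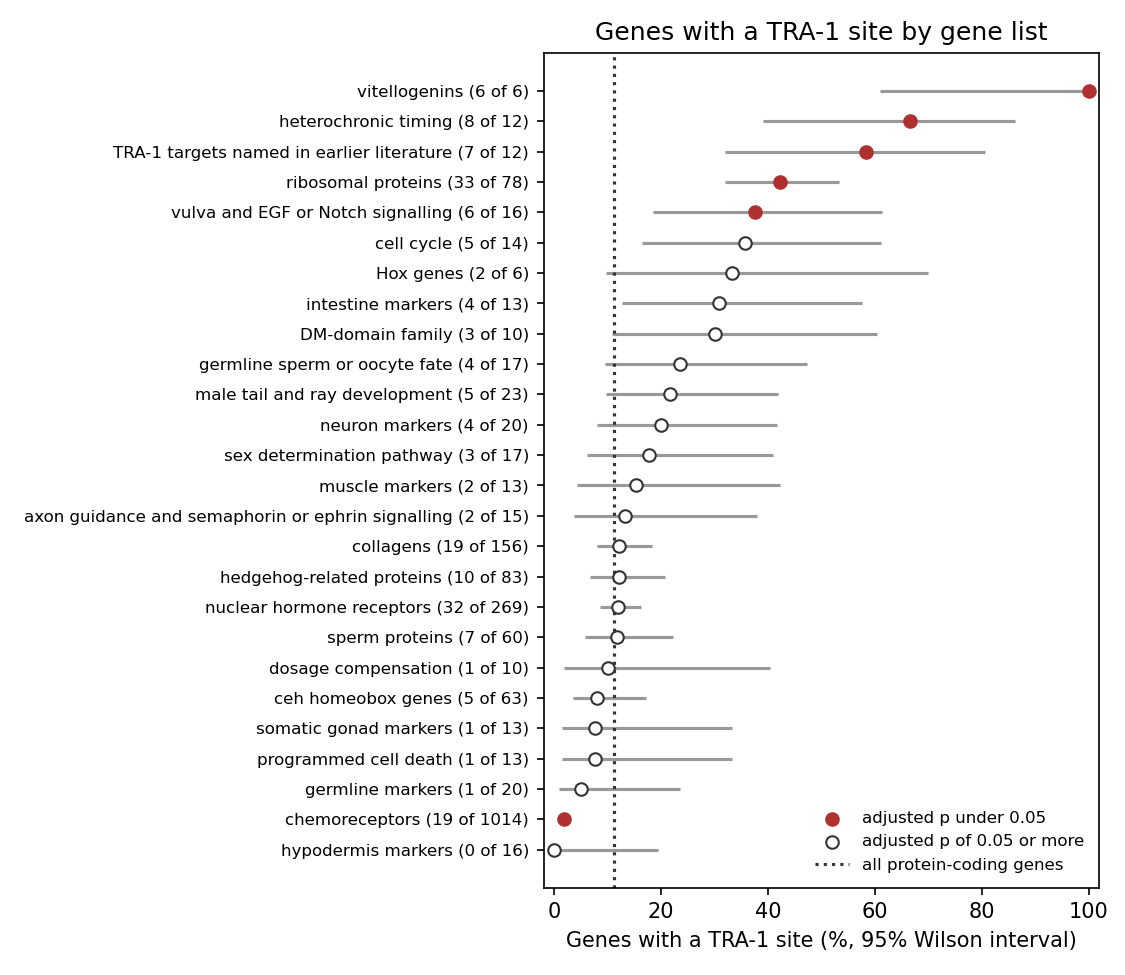
Share of genes with a TRA-1 site (horizontal axis, percent) in each of 26 gene lists (rows, with counts), with 95% Wilson intervals as lines. Filled points passed Fisher's exact test after adjustment, and the dotted line marks the 11.2% of all protein-coding genes with a site.

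Genes transcribed as short structural RNAs were frequent among the sites. Summits within 100 bp of a tRNA gene made up 10.5% of the main list (283 sites), against a mean of 0.19% for random placements, and 292 of the 612 tRNA genes (47.7%) had such a site. Small nucleolar RNA genes accounted for 2.66% of sites, against 0.113%, and small nuclear RNA genes for 0.703%, against 0.035%. Each of these gave a two-sided permutation p = 0.002, the smallest that 1000 placements can give. No site of the main list lay near the 20 annotated rRNA genes, where random placements put a mean of 0.0124% of sites, too few for a lack of sites to be told from chance. A ranked site within 100 bp of an rRNA gene on V (signal 129.2) passed the threshold but was left out of the main list. In replicate 1 alone and replicate 2 alone, the shares were 11.2% and 15.4% for tRNA genes, 3.92% and 4.43% for small nucleolar RNA genes, and 0.832% and 1.11% for small nuclear RNA genes.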

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

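The tests of repeated exact cores and of the X share of sites that did not pass were chosen after the result was seen, as were the 7-mer background of sites that did not pass and the versions without sites near tRNA genes. For the core at tRNA and ribosomal protein sites, a condition was added after its value was seen, given below.

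A signal outside the main list stood out: 75 sites of the ranked list passed the threshold and were left out of the thresholded list, among them the strongest peak of all, on X at 15811108, with a signal of 3303 against 894.7 for the strongest main site. Of these 75 sites, 59 lay in no protein-coding gene or its upstream region and 1 lay at an rRNA gene on V, and why they were left out was not tested.

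X held 24.6% of sites. tRNA genes on X account for part of this at most, since without sites near tRNA genes the lower Wilson bound of the X share was 20.08%, above X's 17.7% of the genome. Ranked sites that did not pass were not in excess on X, with an upper bound of 16.77% for their X share. This counts weak peaks and does not measure the level of signal, so it cannot decide whether the background on X was raised. Whether X sites hold the core more often cannot be told apart from no difference, with an odds ratio of 0.794 (95% interval 0.381 to 1.53). No biological explanation was tested, since the series has 1 group.

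The excess at summits of the core with at most 1 mismatch was small. Base composition may account for it: the core's centre to flank ratio was 1.95, and 263 of the 503 other orders of its bases had a ratio as high. The exact core lay at 8 summits, against 1 window in each flank (exact McNemar tests, two-sided, p = 0.0391 each). Anywhere in a site it was found at 12 sites, and fewer of the other orders, 20 of 503, were found as often. Exact cores repeated within a site are too few to decide, since 2 sites, at snpc-1.3 and fog-3, held at least 2, with an exact Poisson lower bound of 0.242, and 1 of the 503 other orders had as many.

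Whether sites at tRNA genes reflect a general enrichment of accessible or highly transcribed DNA could not be decided. Ranked sites that did not pass also lay near tRNA genes more often (0.231%) than the highest of the random placements (0.21%), though far below the 10.5% of main sites. They are weaker peaks of the same experiment, so weak TRA-1 binding would give the same excess. Their share also passed the highest placement near small nucleolar RNA genes (0.175% against 0.163%). Near small nuclear RNA genes their share (0.0604%) was above the random mean of 0.0397% (permutation test, two-sided, p = 0.012) but below the highest placement (0.0644%). Near rRNA genes, with 3 sites, their share (0.00394%) was below the random mean of 0.0135% (permutation test, two-sided, p = 0.022) and the highest placement (0.0329%). For ribosomal protein genes such an enrichment was not tested. The core was present at 2.85% of the tRNA and ribosomal protein sites. By the rule as first written this would speak for the core, since the lower Wilson bound of 1.5% lay above the 1.09% of the flanks. A comparison with other orders of the same bases, added after that value was seen because summits are richer in G and C, found a share as high for 180 of 503 orders, so whether the core draws TRA-1 to these sites cannot be told apart from base composition.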

How the results depend on the processing

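The alternatives at an IDR of at most 0.001, without sites near tRNA genes, and with sites that did not pass as the background of words were chosen after seeing the data. The planned threshold of 0.01 moved nothing, since the authors' lists already met it. Replicate overlap, the promoter share, the X share, the core share and the tRNA share kept their direction and their side of the threshold under every alternative run. The number of sites was 1321 at an IDR of at most 0.001 and 1355 to 1682 in the replicates alone. The Spearman correlation of the replicates fell to 0.3055 over all ranked sites. The difference in the core between the strongest and weakest sites, which did not pass in the main list, passed in the second thresholded list at 1.51 percentage points and ranged from -0.238 without replicate 2 to 1.18 without replicate 1. Words more frequent at summits numbered 826 of length 6, of which fewer exist, and 803 against sites that did not pass. Lists past the threshold numbered 4 with promoters only and 11 with each site given to its nearest start only. The 11 include the DM-domain family (Fisher's exact test, adjusted p = 0.0345), male tail (0.0251), cell cycle (0.0313), intestine (0.0251) and neuron (0.0341) lists, which did not pass in the main analysis. The heterochronic list did not pass with promoters only (0.139). The vulval, EGF or Notch list passed in the stronger sites by signal (0.0112) and with the nearest start only (0.0419), and did not pass in any other alternative that changed the sites, genes or test, among them an IDR of at most 0.001 (0.061) and no sites near tRNA genes (0.0762). The cause was not tested.

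Among lists that did not pass in the main analysis, the bound share of 12 crossed to the other side of the share of the remaining genes at least once, in 42 cases, of which 0 were past the threshold. With promoters only, the bound genes numbered 0 for axon guidance, 3 for hedgehog-related proteins, 5 for collagens and 1 for neuron markers. With the nearest start only, they numbered 6 for hedgehog-related proteins, 5 for sperm proteins, 2 for somatic gonad markers and 2 for hypodermis markers. Against the mean of matched random lists, they numbered 2 for axon guidance, 10 for hedgehog-related proteins and 2 for muscle markers. In the stronger sites by signal, they numbered 1 for dosage compensation, 1 for programmed cell death, 3 for sperm proteins, 1 for somatic gonad markers, 0 for muscle markers and 0 for neuron markers. The same numbers held at an IDR of at most 0.001, where ceh homeobox genes, with 4, crossed too. Without sites near tRNA genes, they numbered 7 for hedgehog-related proteins, 5 for sperm proteins and 15 for collagens. In the second thresholded list, hedgehog-related proteins had 8. In each replicate alone, they numbered 1 for dosage compensation, 1 for programmed cell death, 3 to 5 for hedgehog-related proteins, 7 to 11 for collagens and 1 for somatic gonad markers. In replicate 2 alone, Hox genes crossed with 0 and muscle markers with 0, and in replicate 1 alone they did not, with 2 and 1. In replicate 1 alone, ceh homeobox genes crossed with 5 and neuron markers with 1, and in replicate 2 alone they did not, with 3 and 2. Depth is unknown, so what it limits could not be measured.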

Other observations

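The snpc-1.3 gene, which no list named and which was chosen after its values were seen, had a site 78 bp upstream of its start on chromosome V, with a signal of 111.6 and 3 exact cores. The site was in neither replicate's own thresholded list. Its peak signal was 55.1 in replicate 1 and 56.7 in replicate 2. The heterochronic gene hbl-1 had an exact core at a site 1092 bp upstream of its start (signal 119.4), and sod-4 at a site 164 bp upstream (98.7).

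Exact cores anywhere in a site were found at 12 sites, against a median of 3 for the other orders of the same bases, and 20 of the 503 orders were found as often.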
